A study of Mus musculus with 180 samples.

How the data were processed

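The series held 180 RNA libraries from mouse, 1 for each of 15 tissues of each of 12 mice. Per the labels the mice were female, 6 weeks old, and perfused with PBS and EDTA before collection. Mice 1 to 4 were C57BL/6J mice given PBS, mice 5 to 8 were C57BL/6J mice given 5 mg/kg lipopolysaccharide (LPS), and mice 9 to 12 were B6.129S-Tnftm1Gkl/J mice, which lack TNF, given the same dose. All tissues were taken at 12 hours. Reverse transcription started from the poly(A) tail, so each read tags the 3′ end of a transcript, and the primer carried a barcode for the sample and a 10 bp molecular identifier. The labels do not say whether reads with the same identifier were counted once, so whether 1 count stands for a molecule or a read is not known. The part of Tnf removed in this allele is not given in the labels.

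The authors deposited 1 table of gene values per tissue and 1 table of all libraries, and the same values stood in both. The deposited signal values come from tables named for CPM, but their sums per library ranged from 703690 to 1603067, so they are described here as a signal, scaled by the authors to an effective library size. In every library 100% of the values were whole multiples of 1 step, within 0.1 counts, which gave back whole counts. These summed to 311128 to 2573806 per library, and 1 count corresponded to a signal of 0.322 to 3.6. Replicate pairs within a group (270 pairs) differed by more than counting error in each pair, with a lowest chi-squared per degree of freedom of 1.18. The tables held 13820 genes, of which 11438 to 13559 were above 0 in a library. The authors' processing notes name FastQC, MultiQC and edgeR without versions and the mm10 build. The aligner is not given in the sources used here. Gene symbols with dots in place of hyphens (106) were read with hyphens, and 13555 symbols were found in the GENCODE M21 annotation of GRCm38 (mm10), from which positions were taken.

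Values were transformed to log2(signal + 1). Within each tissue, genes with a signal of at least 1 in at least 4 of the 12 libraries were tested with limma 3.58.1 (trend) in R 4.3.3, with 9 residual degrees of freedom, for 2 comparisons: LPS against PBS mice, and TNF-deficient against wild-type mice, both given LPS. The threshold was a Benjamini-Hochberg adjusted p of 0.05 within each tissue and comparison. The groups compared share no mouse. No TNF-deficient mice without LPS were part of the design, so an effect of the allele or of the strain background cannot be told apart from an effect on the response. Log2 changes are given with the standard error (SE) where 1 is printed, and signals as mean ± SD, n = 4.

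The pathway, tissue marker and cell type lists (46 in all) were tested with limma's fry, where at least 5 members were measured, with adjustment over lists and tissues of a comparison. Fry's PValue tests whether a set's genes move, on balance, one way, and does not compare the set with other genes. Member counts are given over all genes tested and adjusted over the list alone. Differences of a change among tissues were tested by limma's moderated F over 14 tissue differences in a joint fit of the 45 groups. Each tissue was tested against the others in the same fit. For the moderated F, mouse as a replicate block was an alternative. All tissues came from the same mice, and a fit without that block takes libraries as independent. The overlap of the 2 comparisons was set against the number expected if calls were independent, against 20 simulations of an unchanged TNF-deficient group, which leave out any effect, and against 6 divisions of the LPS mice in which separate mice served each comparison. Since the LPS mice enter both comparisons with opposite sign, their sampling error alone favours opposite calls.

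Named genes were chosen by rule. A gene was eligible where its adjusted p was below the threshold, its mean signal was at least 10 in the higher group, each library of 1 group lay above each library of the other, and its symbol was not that of a predicted, clone, ribosomal, mitochondrial or antigen receptor gene. The rule took, per comparison and direction, the 10 genes eligible in the most tissues, per tissue the 4 with the largest change in each direction for LPS against PBS and 3 for the comparison of genotypes, Tnf, Lta, Ltb and the TNF receptor genes in every tissue, and up to 4 members per list by size of change with any member that moved against its list. The text names a subset. So for every gene taken by the tissue part of the rule, 4 of 4 libraries lay on its side of the other 4. The tests, thresholds, lists, this rule and most alternatives were fixed before the data were examined. The tests of each tissue against the others were not part of that plan.

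Alternatives were a pseudocount of 0.25, no filter, rescaling by median-of-ratios size factors, a fit on the 2 compared groups alone, leaving out each mouse in turn, and edgeR 4.0.16 quasi-likelihood on the recovered counts. After the data were seen, fits without the libraries with the highest signal of another tissue's markers were added, as were 2 counts without kidney genes in the lymph node. The steps were checked on simulated data. Libraries were drawn from a negative binomial model with the mean values, library sizes and dispersions of liver or spleen, each gene drawn independently. Of 4-fold changes planted in them, limma called 68.2% and 77.3% in liver and 71.2% and 74.2% in spleen for the 2 comparisons. Of 2-fold changes it called 25.4% and 29.9% in liver and 53.7% and 52.2% in spleen. False calls were 3 of 78, 1 of 83, 10 of 103 and 7 of 98, and none of the planted calls had the wrong sign. Of 200 random lists, fry gave 12 in liver and 10 in spleen below 0.05. In the tissue-difference simulation 34 of 100 planted 2-fold and 77 of 100 planted 4-fold differences were called, with 23 false calls beside 111 on changed genes. Plots and tables were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Every library was used. Some genes that the rule took are not reported here.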

Results

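RNA from 15 tissues of 12 female mice was measured by 3′ tag sequencing, 12 hours after PBS or 5 mg/kg LPS, a bacterial cell wall component that activates innate immunity. There were 4 wild-type mice given PBS, 4 wild-type mice given LPS and 4 TNF-deficient mice given LPS, and each mouse gave 1 library per tissue. Total counts per library ranged from 311128 to 2573806. By tissue they ran from 1456808 to 2561546 in bone marrow, 473854 to 2573806 in brain, 311128 to 1342177 in brown fat and 493597 to 1270361 in colon. They ran from 920465 to 2061591 in heart, 1406116 to 2363140 in inguinal lymph node, 1084176 to 2106453 in kidney and 788203 to 1341877 in liver. Lung libraries held 519028 to 1470100 counts, muscle 733938 to 1268163, skin 848142 to 2041017 and small intestine 1051216 to 2497933. Spleen held 433575 to 912730, thymus 625878 to 1058523 and white fat 537156 to 1230206. At this depth 1 count stood for a signal of 0.322 to 3.6, so a signal of a few units rested on few counts.

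The comparison of LPS with PBS mice asks what LPS changed in each tissue. Between 4.3% of tested genes in brain and 38% in kidney passed the threshold. A set of 40 genes was higher in all 15 tissues. The guanylate-binding protein Gbp2, which acts against intracellular pathogens, rose with a median log2 change over tissues of 2.73, and the metallothionein Mt2, which binds zinc, by 2.82. The acute-phase protein gene Saa3 rose by 1 in the tissue with the smallest change and 5.38 in the tissue with the largest (median 2.75), and the LPS co-receptor gene Cd14 by 1.04 to 6.03 (median 2.42). Timp1, an inhibitor of matrix proteases, Socs3, a feedback inhibitor of cytokine signalling, Iigp1, an interferon-inducible GTPase, and the chemokine Ccl5 also rose in all 15 tissues, by medians of 2.54, 2.39, 2.32 and 2.16. At least 10 tissues shared 387 higher genes, where independent calls would give 0.00115, though the tissues came from the same mice and their calls are not independent.

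Fewer genes fell across tissues: 76 were lower in at least 10 tissues (0.00212 if independent), although 8225 were lower in at least 1 tissue, against 6205 higher. The secreted factor Angptl2 fell in 13 tissues (median log2 -1.73) and the stromal chemokine Cxcl12 in 13 (-0.93). Cavin2, a component of caveolae, and the water channel Aqp1 each fell in 13, with medians of -1.18 and -1.05 over the 12 in which each was eligible.

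**Figure D1:**
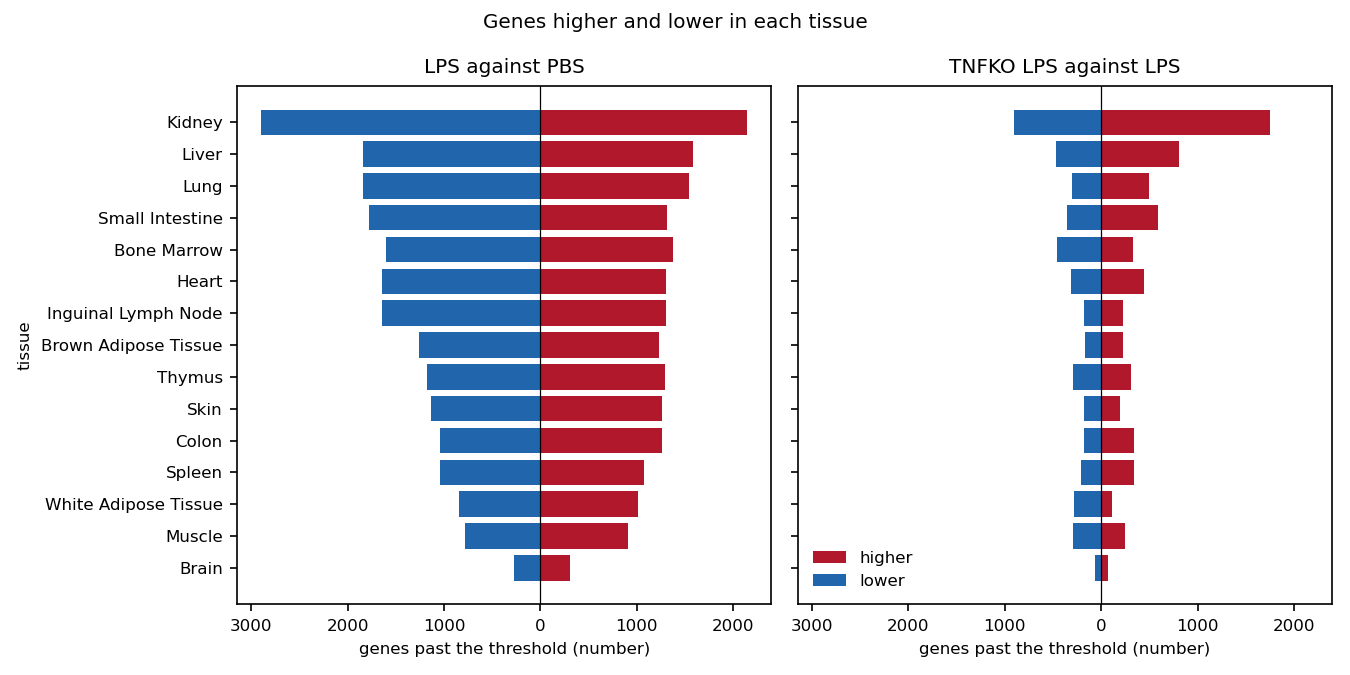
Number of genes past the threshold in each tissue, higher to the right in red and lower to the left in blue, for LPS against PBS (left panel) and TNF-deficient LPS against wild-type LPS mice (right panel). Kidney had the most in both (2143 higher and 2894 lower with LPS) and brain the fewest (308 and 269).

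By list, several groups of genes moved one way in nearly all tissues and others moved apart. The guanylate-binding and interferon-gamma-inducible genes were called higher in 15 tissues, where 278 of 345 gene and tissue tests rose and 1 fell (295 and 2 adjusted over the list alone). The glucocorticoid-responsive and metallothionein genes rose in 15 (198 higher, 6 lower of 270; 216 and 10 adjusted over the list alone), as did NF-kB pathway targets (206 and 5 of 330; 232 and 6 adjusted over the list alone) and chemokines (194 and 14 of 358; 220 and 17 adjusted over the list alone). The p53 and apoptosis genes rose in 15 (120 and 7 of 270; 138 and 11 adjusted over the list alone), though the call in brain was lost without mouse 1, 3, 7 or 8 (adjusted p = 0.052, 0.06, 0.075 and 0.081). The acute-phase genes rose in 14 tissues (218 and 2 of 403, or 234 and 2 adjusted over the list alone), as did MHC class I presentation (193 and 2 of 240, or 206 and 2 adjusted over the list alone). In tissues other than liver, liver markers stood at 0.27% to 0.82% of their level in liver of PBS mice, as group medians. Whether such signal adds to the acute-phase rises outside liver was not tested.

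The interferon-stimulated genes rose in 14 tissues (395 and 14 of 510; 423 and 20 adjusted over the list alone), with medians of 2.42 in inguinal lymph node and 2.19 in bone marrow. Endothelial activation genes rose in 14 tissues (103 and 13 of 208; 113 and 16 adjusted over the list alone), and the bone marrow call was lost without mouse 2, 3, 5 or 7 (adjusted p = 0.063, 0.084, 0.083 and 0.062). Cytokines and growth factors rose in 14 (90 and 11 of 215; 100 and 13 adjusted over the list alone), and the brain call was lost without mouse 2, 4 or 7 (adjusted p = 0.062, 0.063 and 0.053). Neutrophil markers were called higher in 11 tissues and lower in bone marrow (62 and 12 of 269; 67 and 12 adjusted over the list alone). Of the 11 calls 8 were kept whichever library was left out, and in the other 3, colon, kidney and muscle, at most 2 members passed. Fibroblast markers fell in 9 tissues (17 higher and 58 lower of 180; 17 and 71 adjusted over the list alone), a call kept in 7 whichever library was left out. T cell markers fell in 5 tissues (kept in 4; 5 higher and 43 lower of 240, 5 and 50 adjusted over the list alone) and B cell markers in 3 (kept in 3; 3 and 32 of 195, 2 and 34 adjusted over the list alone). MHC class II presentation fell in 6 (kept in 6) and rose in 3 (kept in 2), with 12 tests higher and 38 lower of 150 (13 and 44 adjusted over the list alone). Cholesterol and lipid synthesis fell in 7 tissues (kept in 5) and rose in 2 (kept in 1), and oxidative phosphorylation fell in 6 (kept in 5) and rose in spleen (4 of 25, 5 adjusted over the list alone, adjusted p = 0.019), a call lost without mouse 2 (0.053).

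**Figure D2:**
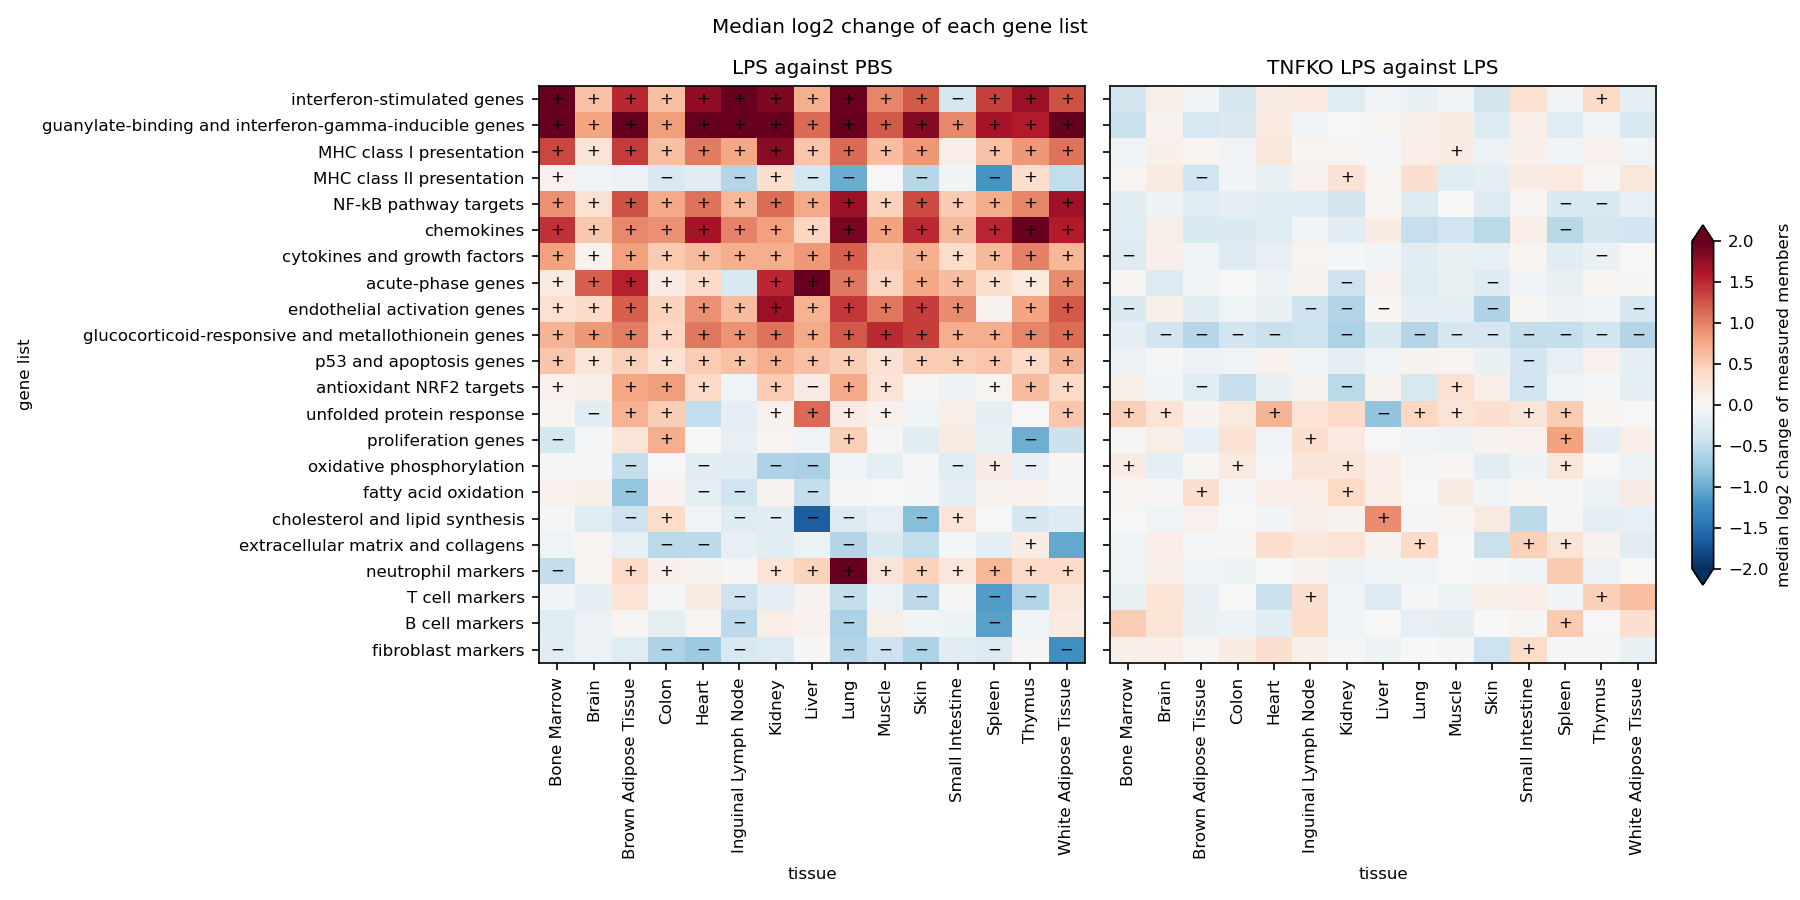
Median log2 change of 22 gene lists in 15 tissues, for both comparisons, on a colour scale from -2 to 2, where + and - mark lists called higher or lower by the test on the set. Guanylate-binding and interferon-gamma-inducible genes are marked higher in 15 tissues with LPS, and the glucocorticoid-responsive and metallothionein genes lower in 12 in TNF-deficient mice.

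In liver, Saa2 (mm10 chromosome 7, 46751790 to 46754313) rose from 169 ± 17.8 (SD, n = 4) in PBS mice to 17130 ± 1690 in LPS mice (log2 6.66, SE 0.1, adjusted p = 5.5e-28), Saa1 by 6.46 and the protease inhibitor A2m from 1.85 ± 1.44 to 306 ± 70.4 (log2 6.91). Of 27 acute-phase genes 22 rose and 1 fell, Crp by -0.64 (23 and 1 adjusted over the list alone, median 2.33, adjusted p = 3.4e-09). Of 20 liver markers 18 fell (18 lower and 2 higher adjusted over the list alone, median -1.94, adjusted p = 2.8e-07), against 2 higher, Arg1 and Tat. Among those that fell were Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-4.96), and the bile acid transporter Slc10a1 (-3.97). Cholesterol and lipid synthesis genes fell in 21 of 23 cases (21 adjusted over the list alone, median -1.65, adjusted p = 4.2e-06), and 14 of 17 unfolded protein response genes rose and 1 fell (15 and 2 adjusted over the list alone, median 1.13, adjusted p = 0.00011), with the chaperone Hspa5 at 1.93. In all 1581 genes rose and 1841 fell.

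Kidney had the largest counts, 2143 genes higher and 2894 lower. Cd14 rose from 22.1 ± 3.02 to 1340 ± 302 (log2 5.84, SE 0.23, adjusted p = 3.3e-16), the fibrinogen chain Fgg from 90.8 ± 6.85 to 3886 ± 310 (5.4), and Havcr1, a marker of injured proximal tubule, from 3.6 ± 1.17 to 165 ± 25.4 (5.2). Gatm, which makes the precursor of creatine, fell from 1233 ± 15 to 51.3 ± 28.5 (-4.69), and Acmsd, an enzyme of tryptophan breakdown, fell as far (-4.69). Of 16 kidney markers 15 fell (16 adjusted over the list alone, median -1.49, adjusted p = 2.8e-07), with the transporters Slc5a12 (-4.24) and Slc12a1 (-2.7) and the hormone Kl (-2.85). The 25 oxidative phosphorylation genes all fell (25 adjusted over the list alone, median -0.62, adjusted p = 4e-07). MHC class I presentation rose in 15 of 16 members (15 adjusted over the list alone, median 1.8, adjusted p = 8.8e-07), further than in the other tissues (median difference 1.07, adjusted p = 4.5e-17).

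In lung, neutrophil markers rose in 17 of 19 cases (19 adjusted over the list alone, median 2.95, adjusted p = 2.4e-07), including Trem1 (4.86) and S100a8 (3.73), further than in other tissues (median difference 2.7, adjusted p = 5.5e-49). Saa3 rose from 319 ± 16.1 to 13510 ± 2790 (log2 5.38, SE 0.12, adjusted p = 2.3e-21), the neutrophil chemokine Cxcl2 by 4.96, and Il1b and Il6 by 4.25 and 3.84. Lung markers fell in 10 of 14 cases, with the surfactant genes Sftpb (-1.48) and Sftpc (-1.36) lower and Sftpd higher (0.73); adjusted over the list alone 10 fell and 1 rose (median -0.74, adjusted p = 2.5e-05). MHC class II presentation fell in 8 of 10 members and rose in 1 (8 and 1 adjusted over the list alone, median -0.99, adjusted p = 0.0012), and of 14 endothelial markers 9 fell and 2 rose (10 and 2 adjusted over the list alone, median -0.54, adjusted p = 0.00029), with the receptors Tek (-2.52) and Tie1 (-1.83) lower. The apelin receptor Aplnr (-4.18) and the integrin Itga8 (95.9 ± 22.1 to 6.49 ± 5.45, -3.89) had large falls. In all 1544 genes rose and 1842 fell, or 1795 and 1686 after rescaling by median of ratios and 1912 and 1844 with edgeR.

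In heart, the 16 MHC class I presentation genes all rose (16 adjusted over the list alone, median 1.04, adjusted p = 7.2e-05). Iigp1 rose from 124 ± 12.6 to 1984 ± 622 (log2 3.93, SE 0.15) and P-selectin, Selp, by which activated endothelium captures leukocytes, by 3.94. Asb2 fell from 240 ± 18.2 to 18.2 ± 11 (-3.8). Of 13 heart markers 8 fell and 2 rose (9 and 2 adjusted over the list alone, median -0.41, adjusted p = 2.1e-05): the channel Kcnj3 (-2.37) and the calcium pump regulator Pln (-1.39) fell, while the natriuretic peptide Nppb rose (1.53). Oxidative phosphorylation fell in 17 of 25 members (20 adjusted over the list alone, median -0.23, adjusted p = 2.8e-06). In all 1307 genes rose and 1641 fell, or 1493 and 1400 after rescaling by median of ratios.

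In brown fat, 9 of 13 brown adipocyte markers fell and 1, Kng2, rose (9 and 2 adjusted over the list alone, median -1.05, adjusted p = 0.00044), with Otop1 (-2.48), the thyroid hormone activating deiodinase Dio2 (-2.41) and the beta-adrenergic receptor Adrb3 (-2.08). Fatty acid oxidation genes fell in 15 of 21 cases (16 adjusted over the list alone, median -0.77, adjusted p = 0.00031) and oxidative phosphorylation in 23 of 25 (25 adjusted over the list alone, adjusted p = 0.00051). Thrsp, a regulator of fatty acid synthesis, fell from 2180 ± 475 to 226 ± 95.8 (log2 -3.36, SE 0.27). Haptoglobin, Hp, rose from 925 ± 114 to 13430 ± 1350 (3.86) and heme oxygenase, Hmox1, from 26.9 ± 3.85 to 401 ± 126 (3.81). In all 1232 genes rose and 1258 fell, or 1474 and 1314 with edgeR. Without mice 7 and 8, which left 2 LPS mice, the total of 2490 was 1494. Skeletal muscle markers stood at 1.16% to 5.23% of their muscle level in the LPS libraries of this tissue and at 0.68% to 2.05% in the PBS libraries.

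In white fat the growth factor Csf3, which drives neutrophil production, rose from 4.36 ± 3.06 to 182 ± 131 (log2 5.19, SE 0.48, adjusted p = 3.2e-08), Serpina3m by 4.68 and the T cell attractant Cxcl9 from 92.8 ± 9.95 to 2237 ± 583 (4.54). NF-kB pathway targets rose in 18 of 22 cases (20 adjusted over the list alone, median 1.7, adjusted p = 5.3e-05). Fibroblast markers fell in 8 of 12 cases (10 adjusted over the list alone, median -1.23, adjusted p = 0.00033), with Fap (-1.92) and Lum (-1.53). The lactate receptor Hcar1 fell by -3.75. In all 1015 genes rose and 846 fell.

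Muscle had the largest rise of glucocorticoid-responsive and metallothionein genes, in 15 of 18 cases (16 adjusted over the list alone, median 1.49, adjusted p = 1.6e-07), further than in the other tissues (median difference 0.75, adjusted p = 1.2e-07), with Mt2 (3.51), Cebpd (2.92) and the cell cycle inhibitor Cdkn1a (2.8). The neutrophil chemokine Cxcl1 rose by 3.85 and Depp1 from 52.9 ± 6.7 to 715 ± 82.4 (3.73). The nicotinamide riboside kinase Nmrk2 fell from 201 ± 73.8 to 13 ± 5.73 (-3.91) and the myogenic factor Myod1 from 30 ± 3.56 to 2.29 ± 2.12 (-3.51). In all 910 genes rose and 780 fell.

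In skin, keratinocyte genes fell: 9 of 12 skin markers (10 adjusted over the list alone, median -0.83, adjusted p = 9.1e-06), with the keratins Krt1 (-2.81), Krt5 (-2.22) and Krt14 (-1.8). Cholesterol and lipid synthesis fell in 17 of 23 cases (17 adjusted over the list alone, median -0.85, adjusted p = 9.7e-05), with Sqle (-2.16). Saa3 rose from 277 ± 6.43 to 7748 ± 1020 (log2 4.79, SE 0.17), the pattern receptor Ptx3 by 4.59 and Clec4e by 4.47. Thymus markers, such as Rag1 (-1.78), fell in 6 of 13 cases in skin (7 adjusted over the list alone, adjusted p = 0.00082), where signal carried over from thymus was not measured. T cell markers fell there in 4 of 16 cases (6 adjusted over the list alone, median -0.52, adjusted p = 0.02), a call lost without mouse 1, 3, 5 or 6 (0.056, 0.055, 0.058 and 0.054). Fibroblast markers fell in 6 of 12 and rose in 1 (8 and 1 adjusted over the list alone, median -0.62, adjusted p = 0.025), a call lost without mouse 1, 4 or 6 (0.055, 0.053 and 0.051). In all 1265 genes rose and 1132 fell.

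In the small intestine, Reg3g, a secreted lectin that kills bacteria, rose from 427 ± 156 to 6122 ± 939 (log2 3.9, SE 0.2, adjusted p = 2.5e-11) and Reg3b by 3.49. Lactase, Lct, fell from 390 ± 48.2 to 33.2 ± 16.6 (-3.68) and the brush border phospholipase Plb1 from 84 ± 11.7 to 5.11 ± 3.59 (-4.01). Of 20 antimicrobial epithelial genes 6 rose and 4 fell, among the latter the Paneth cell lysozyme Lyz1 (-0.6; 7 and 4 adjusted over the list alone, adjusted p = 0.00011). Unlike in the other 14 tissues the interferon-stimulated genes were called lower (median -0.35), but that call was lost without mouse 1, 2, 4, 5, 6 or 8 (adjusted p = 0.062, 0.061, 0.092, 0.079, 0.095 and 0.065) and with 2 groups only (0.078). Plasma cell markers fell in 3 of 7 cases (3 adjusted over the list alone, adjusted p = 0.00059), with the joining chain Jchain (-1.47). Summed pancreatic enzyme signals ran from 531 to 3200 in the PBS libraries and from 205 to 523 in the LPS libraries. In all 1317 genes rose and 1774 fell.

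In colon, antimicrobial epithelial genes rose in 12 of 20 cases (12 higher and 1 lower adjusted over the list alone, median 0.89, adjusted p = 2.4e-05), with the protease inhibitor Slpi from 11.1 ± 3.47 to 267 ± 85.6 (log2 4.46, SE 0.2), the oxidase maturation factor Duoxa2 (3.9) and Reg3b (3.57), whereas Ang4 fell (-1.76). Proliferation genes rose in 15 of 26 cases (18 adjusted over the list alone, median 0.72, adjusted p = 0.00062) and differed from other tissues (median difference 0.76, adjusted p = 3e-08). Cholesterol and lipid synthesis rose in 11 of 23 cases and fell in 2 (11 and 2 adjusted over the list alone, median 0.36, adjusted p = 0.0022). Fibroblast markers fell in 6 of 12 cases and rose in 1 (8 and 1 adjusted over the list alone, median -0.62, adjusted p = 7.9e-05). In all 1264 genes rose and 1038 fell.

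In bone marrow all 34 interferon-stimulated genes rose (34 adjusted over the list alone, median 2.19, adjusted p = 2.1e-06). Il6 rose from 1.75 ± 0.539 to 51.8 ± 24.5 (log2 4.13, SE 0.34, adjusted p = 8.4e-10) and Serpina3g from 25.8 ± 4.83 to 447 ± 144 (4.01). Neutrophil markers fell in 10 of 19 cases and rose in 4 (10 and 4 adjusted over the list alone, median -0.48, adjusted p = 0.011), Ly6g from 66.6 ± 6.21 to 7.34 ± 1.75 (-3.04), and erythroid markers fell in 13 of 14 (13 lower and 1 higher adjusted over the list alone, median -0.55, adjusted p = 0.00015), with the erythroid factor Klf1 at -1.18. Lung markers fell as well, in 10 of 14 cases, and rose in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.0019). In tissues other than lung these markers stood at 0.58% to 1.97% of their level in lung of PBS mice, as group medians. Carried-over lung signal was therefore not told apart from a change in bone marrow. In all 1381 genes rose and 1602 fell, or 1511 and 1478 after rescaling.

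In spleen, B cell markers fell in 11 of 13 cases (11 adjusted over the list alone, median -1.09, adjusted p = 0.00013), T cell markers in 12 of 16 (15 adjusted over the list alone, median -1.12, adjusted p = 1.5e-05) and MHC class II presentation in 9 of 10 (9 adjusted over the list alone, median -1.18, adjusted p = 3.8e-06), while neutrophil markers rose in 11 of 19 (11 higher and 1 lower adjusted over the list alone, median 0.67, adjusted p = 0.0012). The low-affinity IgE receptor Fcer2a fell from 127 ± 21.4 to 14.3 ± 7.19 (log2 -3.22) and the iron exporter Slc40a1 from 226 ± 7.59 to 19.6 ± 4.75 (-3.5, SE 0.2). Interferon-stimulated genes rose in 31 of 34 cases (32 adjusted over the list alone, median 1.37, adjusted p = 8.7e-07). Pancreatic genes were among the higher genes, with Amy2a3 listed at 0 in PBS mice and at 23.3 ± 15.2 in LPS mice, and the summed pancreatic enzyme signal was 489, 357, 62.8 and 82.9 in LPS mice 5 to 8 and 10 to 12.9 in PBS mice. It was 98.8 in TNF-deficient mouse 10 and 7.87 to 12.1 in the other TNF-deficient mice. In all 1079 genes rose and 1040 fell, or 880 and 1163 without mice 5 and 6.

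In thymus, chemokines rose in 21 of 24 cases and fell in 1 (21 and 1 adjusted over the list alone, median 2, adjusted p = 9e-07), with Ccl3 from 0.744 ± 0.505 to 95.8 ± 30.6 (log2 5.79, SE 0.29) and Ccl4 from 6.28 ± 0.936 to 257 ± 61.9 (5.12). All 13 thymus markers fell (13 adjusted over the list alone, median -1.08, adjusted p = 1.9e-05), with the thymoproteasome subunit Psmb11 from 62.7 ± 6.44 to 5.01 ± 2.07 (-3.48) and the pre-T cell receptor gene Ptcra (-2.45), and 24 of 26 proliferation genes fell (26 adjusted over the list alone, median -0.98, adjusted p = 6.2e-06). T cell markers fell in 12 of 16 cases and rose in 1 (14 and 1 adjusted over the list alone, median -0.58, adjusted p = 0.00017). Monocyte and macrophage markers rose in 9 of 18 (10 higher and 1 lower adjusted over the list alone, median 0.51, adjusted p = 0.00044), neutrophil markers in 4 of 18 (4 adjusted over the list alone, adjusted p = 0.00039) and NK cell markers in 3 of 6 (4 adjusted over the list alone, median 0.85, adjusted p = 5.9e-05). In all 1292 genes rose and 1176 fell.

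In inguinal lymph node the 34 interferon-stimulated genes all rose (34 adjusted over the list alone, median 2.42, adjusted p = 2.8e-07), Ifit3 from 57.9 ± 11.7 to 951 ± 271 (log2 4, SE 0.17). B cell markers fell in 9 of 13 cases (9 adjusted over the list alone, median -0.52, adjusted p = 0.00022). The tubule receptor Lrp2, abundant in kidney, fell from 96.8 ± 52.3 to 8.12 ± 1.66 (-3.27), and kidney markers stood at 2.53% to 7.71% of their kidney level in the PBS libraries against 0.51% to 0.66% in the LPS libraries. In all 1304 genes rose and 1642 fell, a total of 2946. Without PBS mice 3 and 4 it was 1880, with more genes higher than lower (977 and 903), and without genes 10 times higher in kidney than in the other tissues of PBS mice it was 2698 (1303 and 1395).

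Brain changed least, with 308 genes higher and 269 lower. Without mouse 1, 2, 3, 7 or 8 the total of 577 was 371, 362, 366, 373 and 368, and it was 1073 with edgeR (613 higher and 460 lower) and 1253 with 2 groups only. Of 26 acute-phase genes 22 rose (24 adjusted over the list alone, median 1.19, adjusted p = 0.00013), with the copper carrier Cp (1.78) and the iron-binding protein Lcn2 (1.57). Ctla2a, a protease inhibitor, rose by 3.01 on the log2 scale (SE 0.18, adjusted p = 2.5e-11) and Fabp7, a fatty acid binding protein of glia, fell from 124 ± 18.1 to 28.1 ± 4.32 (-2.1). Unfolded protein response genes fell in 4 of 17 cases (8 adjusted over the list alone, median -0.22, adjusted p = 0.00074), including Hspa5 (-0.64). Liver markers rose in 7 of 19 cases in brain (8 adjusted over the list alone, median 0.67, adjusted p = 0.01). Liver signal carried over into these libraries was not told apart from a rise in brain, for liver markers or acute-phase genes.

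Limma's moderated F called 8363 of 12441 genes (67.2%) for a difference of the LPS change among tissues, and 8486 with mouse as a replicate block, 8324 of them shared. In simulation this test made 23 false calls beside 111 on changed genes, above 5% of its calls. Liver differed from the other tissues in 3418 genes, brown fat in 2402, kidney in 2094 and spleen in 1912, against 605 in inguinal lymph node and 616 in brain. A2m rose further in liver than elsewhere (difference 6.56, adjusted p = 1.8e-24), Reg3g in small intestine (3.5, adjusted p = 4.4e-43) and Saa3 in lung (2.72, adjusted p = 2.9e-28). Psmb11 fell further in thymus than elsewhere (-3.75, adjusted p = 1.3e-09).

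The comparison of TNF-deficient with wild-type mice, all given LPS, asks which genes differ between the genotypes under LPS. It does not separate an effect on the response from an effect of the allele or strain background. Transcripts of the targeted gene were still counted. Tnf (mm10 chromosome 17, 35199381 to 35202007) stood at 96.8 ± 8.19 in lung of TNF-deficient mice, 20.4 ± 6.95 in wild-type LPS mice and 6.4 ± 2.14 in PBS mice (log2 2.25 between genotypes, SE 0.24, adjusted p = 9.7e-07), and it was higher in TNF-deficient mice in 11 of 15 tissues. It was 69.8 ± 10.1 against 19.2 ± 5.76 in colon (1.84), and the differences in bone marrow (0.13, adjusted p = 0.82), thymus (0.18, adjusted p = 0.79), liver (0.65, adjusted p = 0.42) and brown fat (0.81, adjusted p = 0.22) did not pass. The call in heart (1.35) was lost without mouse 9 (1.19) or 11 (1.17), and that in muscle (1.29) without mouse 5, 7, 9, 10, 11 or 12 (1.24, 1.1, 1.3, 1.29, 1.3 and 1.27) and with a pseudocount of 0.25. The reads tag the 3′ end, and the labels do not say which part of the gene is deleted, so these values do not check the loss of the protein.

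**Figure D3:**
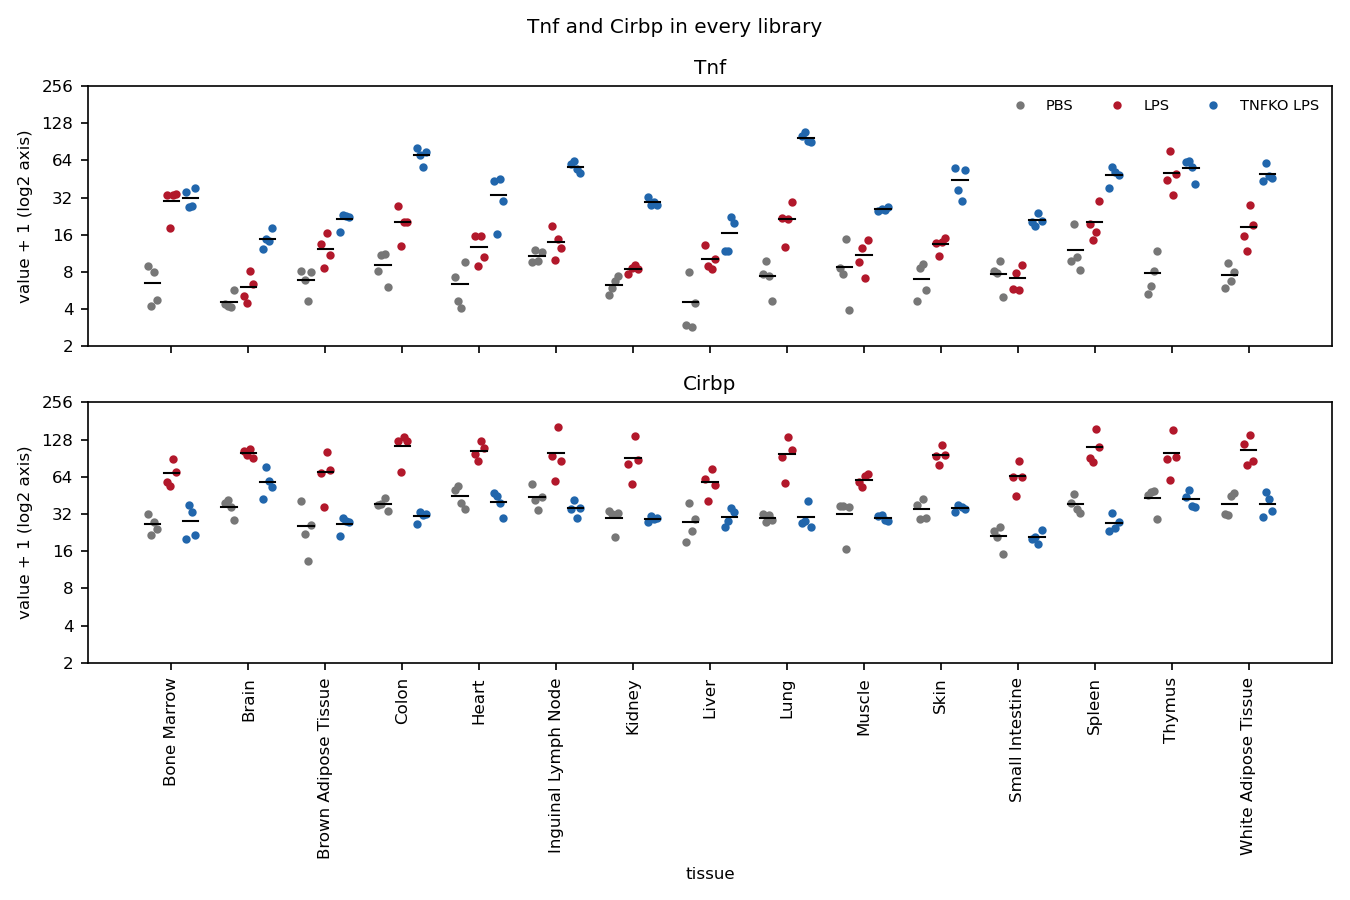
Signal plus 1 of Tnf and Cirbp on a log2 axis in each of 15 tissues, 4 dots per group for the 4 mice and a black line at the mean. In lung the mean of Tnf was 6.4 in PBS, 20.4 in LPS and 96.8 in TNF-deficient LPS mice, and that of Cirbp 28.9, 96.1 and 29.2.

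With LPS alone Tnf rose in wild-type mice by 2.7 in thymus, 2.23 in bone marrow, 1.52 in lung, 1.26 in white fat, 1.15 in colon and 0.97 in skin. It also rose in liver (1.27), a call lost without mouse 1, 3 or 5 (1.11, 1.08 and 1.14) and with edgeR, and in heart (1.03), a call lost without mouse 2, 3, 5 or 7 (0.91, 0.84, 0.92 and 0.92). The receptor gene Tnfrsf1a rose in 11 tissues, by 1.66 in heart and 1.5 in kidney, and was lower in TNF-deficient mice in heart (-0.7), kidney (-0.56) and small intestine (-0.41), the last lost without mouse 5, 7, 8, 9, 10, 11 or 12 (-0.43, -0.34, -0.38, -0.37, -0.44, -0.41 and -0.43) and with 2 groups only. Tnfrsf1b rose by 1.95 in lung and 1.88 in kidney and was lower in TNF-deficient mice in kidney (-0.9), bone marrow (-0.7) and colon (-0.71), the last lost without mouse 7, 8, 9, 10, 11 or 12 (-0.52, -0.68, -0.64, -0.76, -0.69 and -0.75). Ltb fell with LPS in spleen (-2.05), bone marrow (-0.73) and inguinal lymph node (-0.59), and was higher in TNF-deficient mice in spleen (0.74), a call lost without mouse 7 or 8 (0.6 and 0.54). It rose in thymus (0.36), a call lost without mouse 1, 2, 3, 5, 6 or 8 (0.31, 0.32, 0.38, 0.36, 0.26 and 0.28), with a pseudocount of 0.25, without a filter and with 2 groups only. Lta was not in the tables.

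Genes shared over tissues included cold-inducible, chaperone and metallothionein genes. Cirbp (chromosome 10, 80165985 to 80172786) and Rbm3 (chromosome X, 8138975 to 8145880), RNA-binding proteins induced by cold, were lower in TNF-deficient mice in all 15 tissues (median log2 -1.42 and -0.93), as was the ribonuclease Rnaset2b (chromosome 17, 6970634 to 7011299; -1.33). The Cirbp call was lost in brown fat (-1.31) without mouse 5, 7, 8 or 9 (-1.29, -1.1, -1.26 and -1.21) and in liver (-0.9) without mouse 7 (-0.77). Rnaset2b lost its call in brain (-0.87 without mouse 8) and white fat (-0.8, -0.93, -0.91 and -0.58 without mouse 5, 7, 8 or 9). Glo1, which detoxifies methylglyoxal and lies on chromosome 17 (30584936 to 30626871), was higher in 15 tissues (0.97). For genes on the chromosome of Tnf, such as Glo1 and Rnaset2b, a sequence difference carried with the allele was not told apart from an effect of TNF. The collagen chaperone Serpinh1 was higher in 12 (0.92), where the liver call was lost without mouse 9 (0.58), and the endoplasmic reticulum chaperone Hsp90b1 in 11 (0.72), though lower in liver (-0.93).

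By list, the glucocorticoid-responsive and metallothionein genes were lower in 12 tissues, where 100 of 270 tests fell and 6 rose (159 and 12 adjusted over the list alone). In kidney 13 of 18 fell (14 lower and 1 higher adjusted over the list alone, median -0.64, adjusted p = 0.0021), with Mt1 at -2.12. The call was lost in lung without mouse 5 (adjusted p = 0.052), in muscle without mouse 7, 8 or 9 (0.071, 0.05 and 0.055) and in skin without mouse 5, 7, 9 or 11 (0.073, 0.071, 0.06 and 0.065). Unfolded protein response genes were higher in 7 tissues and lower in liver. They rose in 9 of 17 cases in bone marrow (11 adjusted over the list alone, median 0.48, adjusted p = 0.0059), 10 in lung with 1 lower (10 and 2 adjusted over the list alone, 0.42, adjusted p = 0.0019), 8 in spleen (9 and 1 adjusted over the list alone, 0.51, adjusted p = 0.0019) and 2 in muscle (7 adjusted over the list alone, adjusted p = 0.0088). The heart call (10 of 17 with 2 lower, 11 and 2 adjusted over the list alone, adjusted p = 0.016) was lost without mouse 7 (0.064), the brain call (0.027) without mouse 7, 8, 9 or 11 (0.094, 0.064, 0.062 and 0.063) and the small intestine call (0.025) without mouse 5, 6, 7, 10, 11 or 12 (0.062, 0.057, 0.071, 0.061, 0.071 and 0.069).

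Endothelial activation genes were lower in 6 tissues, 3 of which kept the call whichever library was left out (3 tests higher and 35 lower of 208; 6 and 51 adjusted over the list alone). The calls in bone marrow (adjusted p = 0.022), liver (0.033) and white fat (0.024) were lost without mouse 5, 7, 9 or 11 (0.082, 0.055, 0.064 and 0.052), without mouse 6, 7, 8, 9, 10, 11 or 12 (0.054, 0.1, 0.098, 0.095, 0.067, 0.053 and 0.052) and without mouse 5, 7, 8, 9, 11 or 12 (0.056, 0.078, 0.057, 0.059, 0.065 and 0.069). With 2 groups only those in bone marrow and white fat were lost as well (0.074 each). The list was lower in inguinal lymph node (4 of 14, 7 adjusted over the list alone, adjusted p = 0.0036), where the vessel-destabilizing factor Angpt2 went from 50.1 ± 12.7 to 11.3 ± 3.18 (log2 -2.06), in kidney (6 of 14, 7 adjusted over the list alone, adjusted p = 0.0092) and in skin (4 of 14, 9 adjusted over the list alone, adjusted p = 0.0065). The guanylate-binding and interferon-gamma-inducible genes had 19 tests higher and 24 lower of 345 (25 and 45 adjusted over the list alone). Interferon-stimulated genes had 44 tests higher and 26 lower of 510 (70 and 42 adjusted over the list alone). This list was called higher in thymus alone (11 of 34, 16 adjusted over the list alone, median 0.39, adjusted p = 0.025). That call was lost in at least 1 fit leaving out a mouse.

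In kidney the TNF-deficient mice had 1749 genes higher and 903 lower than wild-type LPS mice. These counts were 1466 and 1207 after rescaling by median of ratios and 1400 and 1270 with edgeR. Krt20 (chromosome 11, 99428403 to 99438150), an epithelial keratin, was 360 ± 128 in wild-type and 26.5 ± 15.6 in TNF-deficient mice (log2 -3.79, SE 0.26, adjusted p = 3.8e-10), the transcription factor Sox9 120 ± 70.7 and 13.9 ± 2.16 (-2.73) and Fosl1 -3.46. The fructose transporter Slc2a5 (2.39) and the receptor Adra2b (from 23 ± 11.3 to 114 ± 12.7, 2.36) were higher. Acute-phase genes were lower in 12 of 27 cases (12 adjusted over the list alone, median -0.41, adjusted p = 0.0032), with Lcn2 at -1.54, and antioxidant NRF2 targets in 9 of 15 with 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.0039), with Gclc at -1.29. Fatty acid oxidation genes were higher in 13 of 21 cases and lower in 1 (13 and 1 adjusted over the list alone, median 0.4, adjusted p = 0.007), with Ppargc1a at 1.76, and oxidative phosphorylation in 13 of 25 (13 adjusted over the list alone, adjusted p = 0.0065).

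In liver 811 genes were higher and 467 lower (737 and 512 after rescaling, 815 and 745 with edgeR). Cholesterol and lipid synthesis was higher in 16 of 23 cases and lower in 1, Scd1 (16 and 1 adjusted over the list alone, median 0.94, adjusted p = 0.0065). Acmsd went from 2.94 ± 1.95 to 57.5 ± 9.15 (log2 4.02, SE 0.33, adjusted p = 1.2e-09). Unfolded protein response genes were lower in 10 of 17 cases and higher in 1 (11 and 1 adjusted over the list alone, median -0.79, adjusted p = 0.018), with Hspa5 at -1.91, but the call was lost without mouse 5 (0.056) or 11 (0.052) and with 2 groups only (0.059). Saa2 did not pass and stood at 17130 ± 1690 and 18520 ± 1340.

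In small intestine, 593 genes were higher and 352 lower (463 and 418 after rescaling; 544, 604, 584 and 592 in total without mouse 8, 9, 10 or 11, against 945). The glutathione transferase Gsta1 went from 60 ± 18.4 to 4.75 ± 1.04 (log2 -3.38, SE 0.23, adjusted p = 5.4e-09), and Plb1, lower with LPS, from 5.11 ± 3.59 to 47.3 ± 13.1 (3.16). Extracellular matrix and collagens were higher in 11 of 20 cases (12 adjusted over the list alone, median 0.48, adjusted p = 0.0054) and plasma cell markers in 3 of 7 (3 adjusted over the list alone, adjusted p = 0.0019), with Jchain at 1.36. The class I gene H2-Bl, on chromosome 17 near Tnf (36080115 to 36084223), was higher by 3.79. In colon 336 genes were higher and 175 lower (266 and 229 after rescaling, 376 and 387 with edgeR), and the total of 511 was 835, 296, 306, 302 and 303 without mouse 6, 7, 9, 10 or 12. The sugar phosphate transporter Slc37a2 went from 8.72 ± 8.26 to 53.7 ± 14.5 (2.83) and the growth factor Areg from 44.5 ± 26.4 to 9.87 ± 2.86 (-1.95).

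In lung 491 genes were higher and 302 lower (596 and 602 with edgeR), and the total of 793 was 1348, 515 and 515 without mouse 6, 7 or 8. The deiodinase Dio2 went from 94.1 ± 58 to 8.66 ± 4.62 (log2 -3.09, SE 0.44) and the secreted peptide Prok2 from 12.1 ± 9.85 to 66.2 ± 21.8 (2.57). Extracellular matrix and collagens were higher in 6 of 20 cases (11 higher and 1 lower adjusted over the list alone, median 0.4, adjusted p = 0.0065). In heart 442 genes were higher and 312 lower (369 and 396 after rescaling, 419 and 454 with edgeR; 480 in total without mouse 12, against 754). The calcineurin regulator Rcan1 went from 517 ± 211 to 68.8 ± 28.5 (-2.86, SE 0.24) and Asb2 from 18.2 ± 11 to 60.5 ± 3.87 (1.84).

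In brown fat 231 genes were higher and 167 lower (361 and 454 with edgeR). The total of 398 was 637, 193, 219, 210 and 213 without mouse 6, 7, 8, 11 or 12. It was 107 without mice 7 and 8, whose libraries had the highest skeletal muscle marker signal. That fit kept 2 LPS mice, so having fewer mice was not told apart from the muscle signal. Hmox1 went from 401 ± 126 to 72.5 ± 15.3 (log2 -2.43, SE 0.19) and Adrb3 from 47.7 ± 11.7 to 263 ± 12.5 (2.47). In white fat 107 genes were higher and 280 lower, and the total of 387 was 197, 641, 173 and 186 without mouse 5, 6, 7 or 8. Adrb3 went from 12.5 ± 6.7 to 61.9 ± 19.1 (2.34).

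In muscle 246 genes were higher and 292 lower. Ptx3 went from 701 ± 412 to 91.1 ± 12.6 (log2 -2.72, SE 0.24), and antioxidant NRF2 targets were higher in 6 of 15 cases (6 adjusted over the list alone, median 0.3, adjusted p = 0.0019), with Srxn1 at 1.58 and Hmox1 at 1.38, unlike in the other tissues (median difference 0.52, adjusted p = 2.4e-11). In skin 192 genes were higher and 182 lower (192 and 226 after rescaling), and the total of 374 was 230, 704, 180, 197, 207 and 188 without mouse 5, 6, 7, 8, 9 or 12. The immediate early genes Fos (650 ± 398 to 112 ± 11, -2.33) and Fosb (-2.6) were lower.

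In bone marrow 334 genes were higher and 461 lower, and the total of 795 was 1278, 470 and 395 without mouse 6, 7 or 8. It was 432 without mice 10 and 11, which left 2 TNF-deficient mice. The libraries of mice 10 and 11 had the highest kidney marker signal (0.75% to 3.8% of the kidney level in the TNF-deficient mice and 0.96% to 2.13% in the LPS mice). Cytokines and growth factors were lower in 5 of 14 cases (5 adjusted over the list alone, median -0.26, adjusted p = 0.0019), Il6 going from 51.8 ± 24.5 to 5.14 ± 2.39 (log2 -3.06, SE 0.34), with Il1b at -1.17. The chaperone Hsph1 went from 18.4 ± 5.08 to 56.4 ± 7.99 (1.59). In spleen 343 genes were higher and 213 lower (256 and 251 after rescaling, 318 and 319 with edgeR). The total of 556 was 332, 352, 335, 330 and 369 without mouse 7, 8, 9, 11 or 12. It was 972 without mice 5 and 6, whose libraries had the highest pancreatic enzyme signal. Mouse 6 also had the smallest LPS response in spleen, 68% of that of the other LPS mice. Which of these raised the count was not tested.

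In thymus 306 genes were higher and 288 lower (294 and 300 after rescaling; 594 in total, 347 without mouse 7). T cell markers were higher in 13 of 16 cases (13 higher and 1 lower adjusted over the list alone, median 0.48, adjusted p = 0.0039), with Cd8a at 0.97. The class I gene H2-T10, close to Tnf on chromosome 17 (36115876 to 36121465), went from 23.8 ± 8.44 to 209 ± 19.4 (log2 3.14, SE 0.17, adjusted p = 3.2e-19). In inguinal lymph node 225 genes were higher and 183 lower (191 and 217 after rescaling), and the total of 408 was 625, 124, 154, 242, 165 and 214 without mouse 6, 7, 8, 10, 11 or 12. In brain 73 were higher and 62 lower, and the total of 135 was 40, 32, 225 and 275 without mouse 7, 8, 9 or 10. It was 271 with edgeR (137 higher and 134 lower), 234 after rescaling (138 and 96) and 30 with 2 groups only. Ctla2a was lower in brain by a log2 difference of -1.35 (SE 0.18, adjusted p = 0.0003).

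For the difference between genotypes, 3383 of 12441 genes (27.2%) differed among tissues, 3696 with mouse as a replicate block and 3364 in both, and 2213 without mouse 8. Liver differed from the other tissues in 1094 genes, muscle in 604 and kidney in 528. Acmsd differed in liver (3.96, adjusted p = 8.6e-10) and Cd14 in kidney and liver (-1.88 and -1.93, adjusted p = 2.1e-08 and 3.5e-09).

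Many genes changed by LPS differed in the opposite direction in TNF-deficient mice, though both comparisons use the wild-type LPS mice, which alone favours opposite calls. Summed over tissues, 7739 LPS-changed genes were called in the opposite direction, 3275 of the 18942 higher and 4464 of the 20775 lower, where independent calls would give 1407.8. Simulations of an unchanged TNF-deficient group gave 0.65, but they held only 1.25 calls between genotypes in all, so they do not show how far the shared LPS mice favour opposite calls. Without mouse 7 the sum was 5145. With separate LPS mice for each comparison it was 4050.9 on average, where 729.2 would be independent. In kidney 36.1% of the higher and 51% of the lower genes were called in the opposite direction, Krt20 among them, and in liver 21.3% and 35%. Calls in the same direction numbered 569, against 1339.1 if independent (402.5 against 678.9 on average with separate LPS mice). In muscle, calls in the same direction lay above the expected number, with 110 against 33.3 (65.5 against 14.6 with separate LPS mice). Opposite calls there were still more frequent, 203 against 33.8 (85 against 14.1 with separate LPS mice). With separate LPS mice thymus lay above on average as well (30.5 against 22), as by smaller differences did spleen, white fat, inguinal lymph node and brain. Over the 6 divisions the counts ran from 14 to 45 in thymus, 12 to 41 in spleen and 4 to 16 in white fat. They ran from 5 to 43 in inguinal lymph node and 0 to 2 in brain. Each of these ranges reaches below the average expected count.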

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

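The counts of genes whose change differed among tissues came from tests chosen before the data were examined, and the test of rescaling for Cirbp and Rbm3 was set out before its result was seen. The other tests in this part were chosen after the result was seen.

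Single libraries lay far from the other 3 of their group in 7 of 135 groups and measures tested, where chance gives about 6.8 by Dixon's limit for 4 samples. In bone marrow the Tnf signal of LPS mouse 6 was 17.1, against 32.6, 32.6 and 33.3, and its mean log2 signal of interferon-stimulated genes was 6.93, against 7.6, 7.52 and 7.6. In brown fat the total count of LPS mouse 8 stood apart, at 1.34 in units of 1e+06 counts, against 0.955, 0.939 and 1. Also in brown fat, Tnf was 16 in TNF-deficient mouse 9 (22.3, 21.5 and 21.4), and the interferon-stimulated genes stood apart at 6.11 in TNF-deficient mouse 10. The interferon-stimulated genes stood at 4.35 in heart of PBS mouse 3 (4.57, 4.54 and 4.58) and at 6.77 in white fat of TNF-deficient mouse 10 (6.06, 5.98 and 5.98).

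The change differed among tissues for 8363 genes with LPS and for 3383 genes between genotypes (2213 without mouse 8). With LPS the change of the interferon-stimulated genes was lower in small intestine than in the other tissues (median difference -1.72, adjusted p = 7.5e-20), that of neutrophil markers lower in bone marrow (-0.93, adjusted p = 1e-16) and that of the unfolded protein response lower in brain (-0.43, adjusted p = 1.5e-07). The antioxidant NRF2 targets differed in liver (-0.49, adjusted p = 6.7e-15), where their test was lower (adjusted p = 0.0012) and their mean was -0.24 but their median 0.17. Between genotypes the unfolded protein response differed in liver (-0.82, adjusted p = 8.7e-19).

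In inguinal lymph node, kidney transcripts were present in the PBS libraries, at 3.55%, 2.76%, 6.44% and 7.85% of their kidney level in mice 1 to 4, and at 0.91% to 1.06% in the other 8 libraries. The genes were chosen as abundant in kidney and scarce in the other 13 tissues of PBS mice, without lymph node values. Of 105 such genes 96.2% were called lower with LPS, and of 6 that did not move in kidney itself 5 were called lower here. Random carry-over within the pooled library at a rate common to all libraries was argued against. The 13 kidney markers abundant in kidney, not chosen by their level elsewhere, stood at 2.55% to 7.76% of their kidney level in the PBS libraries here, and every PBS library of 13 of 13 other tissues lay lower (at most 1.83%, in liver). Only PBS libraries were compared, and some bone marrow libraries of TNF-deficient mice also held raised kidney marker signal. Carry-over at a rate that differs between libraries was not tested. A candidate explanation is kidney tissue in these samples, and a biological explanation was not tested.

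Genes near Tnf on chromosome 17 were over-represented among those that differed between genotypes in many tissues. Of 473 genes within 25 Mb, 12 were called the same way in at least 8 tissues, against 44 elsewhere (odds ratio 7.48, CI 3.57 to 14.5, Fisher's exact p = 5.3e-07), and the odds ratio was 1.66 for LPS against PBS (CI 1.2 to 2.26, exact p = 0.0018), where no strain difference exists. Rnaset2b, on the same chromosome outside that window, was counted elsewhere. Among genes called the opposite way with LPS in under 50% of their tissues it was 17.3 (CI 5.66 to 49.2), from 7 genes near Tnf that included Glo1, Hspa1b, Psmb9 and Tnf itself. Tnf, the targeted gene, was counted in both, and without it the odds ratios were 6.86 (CI 3.17 to 13.6) and 14.8 (CI 4.48 to 44). Fisher's test takes genes as independent, but neighbours such as Rps2 and Snhg9, measured in the same mice, may not be. The intervals and exact p may therefore overstate the certainty. A strain variant carried with the allele is consistent with these values. A response to LPS that depends on TNF stays open, since 46.8% of the gene and tissue pairs near Tnf (52% without Tnf) were also called the opposite way with LPS, and no TNF-deficient mice without LPS were there to separate them.

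Cirbp and Rbm3 were higher with LPS and lower in TNF-deficient mice in 15 tissues, though the Cirbp call between genotypes was lost in brown fat without mouse 5, 7, 8 or 9 (log2 -1.29, -1.1, -1.26 and -1.21) and in liver without mouse 7 (-0.77). For the rise with LPS the authors' normalization was argued against, since 15 of 15 tissues kept both calls with LPS after median-of-ratios rescaling. The calls between genotypes were not part of this test. In 15 of 15 tissues both genes were higher with LPS within a single strain, but this does not test whether a strain variant lowered them in the TNF-deficient mice, which stays open because no TNF-deficient mice without LPS were measured. Lower body temperature after LPS in mice with TNF is a candidate explanation, because cold induces these genes, but it stays open. The heat shock list was lower with LPS and higher in TNF-deficient mice in 4 of 15 tissues. It was lower with LPS in 9 tissues and higher in spleen, and higher in TNF-deficient mice in 7. Body temperature is not among the labels.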

How the results depend on the processing

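The fits without mice 10 and 11 in bone marrow, 7 and 8 in brown fat, 3 and 4 in lymph node and 5 and 6 in spleen, and the 2 fits without kidney genes, were chosen after seeing the data. The other settings were chosen before. Each fit without a pair of mice kept 2 of the 4 in its group, so having fewer mice was not told apart from the removed signal.

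Counts of genes, list calls and overlaps stayed within 1.5 times of the main count for 36 results with a pseudocount of 0.25 and 36 without a filter. They moved beyond that for 1 result after median-of-ratios rescaling (35 stayed), 3 with 2 groups only (31 stayed), 4 with edgeR (26 stayed) and 57 fits leaving out a mouse (239 stayed). The number of tissues in which a list was called, 104 results, moved beyond it for 5 with a pseudocount of 0.25, 4 without a filter, 14 after rescaling and 29 with 2 groups only, and in 195 fits leaving out a mouse (637 stayed). With mouse as a replicate block both counts of genes that differed among tissues stayed, at 8486 and 3696. No named gene reversed its direction. Results for named genes were weaker in 2574 fits leaving out a mouse, the same in 22757 and stronger in 13. They were weaker for 172 with 2 groups only (1 stronger), 75 with a pseudocount of 0.25, 51 without a filter, 44 with edgeR (4 stronger) and 40 after rescaling (2 stronger). The balance of higher and lower counts turned in some tissues. After rescaling it turned with LPS in bone marrow (1511 higher and 1478 lower), heart (1493 and 1400) and lung (1795 and 1686), and between genotypes in heart (369 and 396), lymph node (191 and 217), skin (192 and 226) and thymus (294 and 300). With edgeR it turned with LPS in brown fat (1474 and 1314) and lung (1912 and 1844), and between genotypes in brown fat (361 and 454), colon (376 and 387), heart (419 and 454), lymph node (197 and 218), lung (596 and 602), skin (192 and 254), spleen (318 and 319) and thymus (294 and 319). With LPS it also turned in lymph node without mice 3 and 4 (977 and 903), and in spleen without mice 5 and 6 (880 and 1163). EdgeR called 1073 genes in brain to 5028 in kidney with LPS, and 271 in brain to 2670 in kidney between genotypes.

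With edgeR the count moved to 1073 in brain with LPS (577 in limma), and between genotypes to 271 in brain, 815 in brown fat and 1198 in lung. After rescaling, brain moved to 234 genes between genotypes. With 2 groups only, brain moved to 1253 genes with LPS and 30 between genotypes, and list calls between genotypes went from 74 to 45. Without mice 10 and 11 bone marrow had 432 genes between genotypes, without mice 7 and 8 brown fat had 1494 with LPS and 107 between genotypes, and without mice 3 and 4 the lymph node had 1880 with LPS. With all mice it had 2698 without genes 10 times higher in kidney than in the other tissues (1303 higher and 1395 lower). Leaving out genes 10 times higher in kidney than in LPS nodes gave 2588, but that choice favours removing genes that fell. Without mice 5 and 6 spleen had 972 between genotypes. With the LPS mice divided between the comparisons, opposite calls were 6288, 2789, 3235, 4075, 5046 and 2872 and same-direction calls 712, 314, 312, 334, 418 and 324, with 2 mice instead of 4 in the LPS group. The cause was not tested for the other changes.

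Leaving out each mouse in turn gave 362 to 544 genes in brain with LPS. Between genotypes it gave 395 to 1278 in bone marrow, 32 to 275 in brain, 193 to 637 in brown fat, 296 to 835 in colon, 480 to 1086 in heart, 124 to 625 in inguinal lymph node and 515 to 1348 in lung. It gave 180 to 704 in skin, 544 to 1239 in small intestine, 330 to 724 in spleen, 347 to 682 in thymus and 173 to 641 in white fat. Kidney stayed between 2054 and 3313, liver between 925 and 1521 and muscle between 361 and 594. Opposite calls ran from 5145 to 11042, list calls between genotypes from 47 to 122, and genes whose genotype difference varied among tissues from 2213 to 3964. The cause was not tested.

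Of 322 list calls with LPS, 319 were kept with the other pseudocount, 320 without a filter, 318 after rescaling and 306 with 2 groups only. Of 74 between genotypes, 71, 74, 68 and 43 were kept. Depth limits what low signals can show, since 1 count stood for a signal of up to 3.6.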

Other observations

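The tests in this part were chosen after the results were seen.

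The LPS response of mouse 6 was smaller than that of the other LPS mice. Over the genes called without it, its change along the mean change of the other mice was a median of 72.8% of that change (64.9% to 83.9% by tissue), and it was the lowest of 4 in 14 of 15 tissues. Mice 5, 7 and 8 stood at 93.4%, 101.8% and 96.9%. Without mouse 6 the list calls between genotypes went from 74 to 122.

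Libraries of the same mouse in different tissues had a median Pearson r across genes of 0.012 over 1260 pairs, after the group mean was taken off. Genes are not independent replicates, and the median by mouse ran from 0.004 to 0.082.

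Among the splits of 8 mice into 4 and 4, 1 of 35, the real split, gave counts of genes and list calls as large. That share is the smallest these splits can give. The other splits mix the groups compared, so the real difference adds to their spread and lowers their counts. They do not by themselves exclude chance. With LPS the highest count of another split was between 0 and 4 genes, where the real counts were 577 to 5037. Between genotypes the highest other counts were 147 in bone marrow (795 real), 11 in brain (135), 99 in brown fat (398), 32 in colon (511), 52 in heart (754), 11 in inguinal lymph node (408), 5 in kidney (2652) and 44 in liver (1278). They were 268 in lung (793), 4 in muscle (538), 7 in skin (374), 64 in small intestine (945), 10 in spleen (556), 30 in thymus (594) and 144 in white fat (387). For list calls they were 1 with LPS (322) and 8 between genotypes (74), and for genes whose change differed among tissues 722 (8363) and 601 (3383). For opposite calls they were 566 (7739) and for calls in the same direction 29 (569), but these follow the number of calls in a split and do not test the direction. In the split with 698 calls between genotypes 566 were opposite, against 7739 of 11118 in the real split.

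Among heat shock genes, Hsph1 was lower with LPS in 12 tissues and higher in TNF-deficient mice in 10, Serpinh1 in 11 and 12, Fkbp4 in 12 and 7, Dnaja1 in 7 and 11, Hspa1b in 6 and 9, and Hspa1a in 3 and 3. Hsp90ab1 was lower in 5 and higher in 2 with LPS, and higher between genotypes in 7. Dnajb1 was lower in 1 and higher in 1 with LPS, and lower between genotypes in 1. Hspa1b lies near Tnf on chromosome 17, so a strain variant carried with the allele was not told apart from an effect of TNF there.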
